A study of Dicentrarchus labrax with 32 samples.

How the data were processed

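Skeletal muscle, testis, brain and liver of European sea bass (Dicentrarchus labrax) were measured by reduced representation bisulfite sequencing (RRBS) and by RNA-seq. RRBS reads cytosine methylation in the CpG-rich part of the genome that a restriction digest releases: bisulfite turns unmethylated cytosines into thymines, and the share of reads that keep a cytosine is the methylation level. Per the labels' protocols, all fish were reared in the high-temperature group of the study: water was raised from 13.5 to 20.5 °C, at about 0.5 °C per day from 7 days after fertilization, and held there until day 68. The fish were sampled under natural conditions at 3 years of age. The study's low-temperature fish belong to another series and are not analysed here, so the comparisons below are between tissues, not between temperatures. Groups are the tissue and assay given in the labels, with 3 RRBS libraries and 5 RNA-seq libraries per tissue.

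Per the labels' protocols, muscle and testis RRBS libraries were made with a custom protocol from 100 ng of DNA, and brain and liver libraries with a commercial kit (Premium RRBS Kit). Tissue and library preparation therefore coincide in the RRBS data: muscle with testis and brain with liver share a preparation. In the 4 other pairs tissue and preparation cannot be told apart. RNA libraries of all tissues were made with the same stranded mRNA kit, per the labels' protocols; whether strand was used in counting is not given in the sources used here. BSMAP 2.90, methylKit, HISAT2 2.1.0, Subread and featureCounts are named in the submitters' processing notes, with no role for each. The genome build and the gene annotation are not given in the sources used here, and coordinates are printed as the deposited files give them.

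The deposited RRBS files hold, for each cytosine of a CpG and each strand, the coverage as a count of reads and the percent of those reads with C and with T, per the file headers. Coverage multiplied by the percent C was a whole number of reads at every position, within 0.0107 of a read. Methylated read counts were recovered from the deposited percent values. The authors' count tables, 1 per tissue, hold raw counts of reads per gene for 26719 gene models with their exon coordinates and summed exon length. They also hold 22 columns that match no sample of this series, which were not used. The gene identifiers of the count tables were looked up in the RefSeq gene table of the species: 0 matched. The files do not pair them with gene names. At most 2 identifiers that are higher and 2 that are lower are printed per comparison. For the same reason the 20 gene lists fixed beforehand could not be matched to the tables and were not tested. Genes lie on 24 linkage groups and on a sequence named UN (5681 genes), with the same sequence names in the RRBS files.

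RNA counts were analysed in R 4.3.3 with edgeR 4.0.16: filterByExpr over the 4 tissues (22293 genes kept), TMM scaling, and the quasi-likelihood F test (glmQLFit, glmQLFTest) in a single fit of all 20 libraries with a term per tissue, with Benjamini-Hochberg adjustment. A gene was called in a pair of tissues at an adjusted p under 0.05. It was called tissue-enriched when it passed in all 3 contrasts of a tissue and was at least 4-fold higher than in each of the other tissues (log2 fold change of at least 2), and tissue-depleted in the mirror case. Levels are CPM (edgeR's cpm) with TMM factors. The named identifiers are the 2 enriched genes with the largest value of their smallest fold change over the other tissues, and the 2 depleted genes by the mirror rule. A fold against a tissue without reads is a lower bound, set at 3 counts over the 5 libraries of that tissue. The spread between fish was the biological coefficient of variation (BCV) that edgeR's common dispersion gives within each tissue, over 10305 genes that pass the filter in every tissue. Genes with a read were also counted after thinning every library, in expectation, to the smallest total of 11565532 counts.

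Methylation was analysed in Python 3.11.15 (numpy 2.4.6, scipy 1.17.1). A cytosine was used with at least 10 reads in every library compared, each strand on its own. Each site was tested with a quasi-binomial logistic model on methylated and unmethylated reads, with the Pearson dispersion moderated across sites by the squeezeVar method of limma 3.58.1 (prior fitted on sites whose expected binomial variance was at least 1 in every library) and not allowed under 1. The limit on sites used for the prior was set after a test on simulated data and before any call on the data was seen. A site was called at an adjusted p under 0.01 and a difference of at least 25 percentage points. Promoter windows ran from 1000 bp upstream to 500 bp downstream of the annotated gene start. Windows with at least 3 such sites were tested on summed reads and called at an adjusted p under 0.05 and a difference of at least 10 points. The sites and promoters named are the 2 called with the largest difference in each direction, where the difference is that of the methylated share of all reads of a tissue and not of the printed means over libraries. Reads printed beside them are totals over the 3 libraries of a tissue. Mean levels were compared with exact permutation tests, two-sided; 3 libraries against 3 cannot give a p under 0.1. Relations between promoter methylation and expression are Spearman correlations across genes, with permutation tests of 100000 resamples. Genes are not independent replicates, and expression was the mean log2 of CPM per kb of gene model, with 0.5 added to each count.

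On simulated counts for 21109 genes with 200 changed in muscle, the RNA fit called all 200 (100% at 8-fold and at 16-fold) and 0 others. On 50000 simulated cytosines for muscle against testis, 37.0% of those changed by 30 points and 87.6% of those changed by 50 points were called, with 0 false calls. For brain against liver these shares were 34.5% and 87.1%, with 1 false call. The simulated spread between libraries was set alike at every cytosine (intraclass correlation 0.02), and only cytosines of intermediate level were changed. In the data the spread varied between sites, so these shares and the few false calls need not carry over.

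The RRBS files listed between 548765 and 1305496 cytosines per library. Between 716007 and 908657 had at least 10 reads, except in liver replicate 2, with 209871. RNA totals ran from 11565532 to 46332560 counts per library. On these totals, without TMM factors, 3 counts are between 0.0647 and 0.259 CPM. Printed levels use TMM factors, with effective library sizes from 3778415 (muscle replicate 5) to 58988006 (brain replicate 2). On that scale 1 read is 0.2412 CPM in muscle replicate 1. The floors used for folds are on the TMM scale too, at 0.117 CPM in muscle, 0.0144 in testis, 0.0116 in brain and 0.0345 in liver. Intervals and floors of this kind cover counting error only. No pair of RNA libraries of a tissue agreed within sampling noise (chi-square per gene of at least 12.3). The labels number the replicates of each tissue. In the RRBS data, libraries with the same number deviated together in muscle and testis (correlations of deviations of 0.23, 0.34 and 0.25), muscle and liver (0.11, 0.15 and 0.11) and testis and liver (0.21, 0.24 and 0.20). Numbers were therefore taken to pair these 3 tissues, by the rule that every same-number correlation is over 0.1. Brain did not pair with any by this rule, and came nearest with testis (0.11, 0.02 and 0.06). No pair of tissues met the rule in the RNA data. There, same-number correlations were all positive for testis and brain (0.016 to 0.137), testis and liver (0.055 to 0.234) and brain and liver (0.008 to 0.106). Libraries with different numbers reached 0.295, 0.312 and 0.073 in these pairs, so a weak pairing is left open. In RRBS this was settled before the calls with and without a replicate block were compared. The alternatives, listed before the data were examined except where said otherwise, covered scaling, filters, DESeq2 1.42.0, coverage limits, Fisher's exact test on pooled reads, no moderation, windows, thresholds, the replicate block and leaving out each library. Nothing in the labels says that the samples came from separate tanks or families, so p-values of tests between libraries measure the spread between these fish. The main RRBS tests have no term for the replicate numbers. The RRBS fit with the replicate block limits the size of its coefficients. Where the tissue named second in a pair is wholly methylated or wholly unmethylated, this limit can distort the fit. Adjusted p-values of such sites with the block are not reliable, and the numbers of sites called with it can be too low. Tests across genes and Fisher's exact test on pooled reads do not measure the spread between fish.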

Results

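The data comprised 32 libraries from adult European sea bass of the high-temperature group: 12 RRBS libraries (3 per tissue) and 20 RNA-seq libraries (5 per tissue) of skeletal muscle, testis, brain and liver. Per the study's design text, these tissues stand for different embryonic layers. RNA totals per library were 11565532 to 16433494 counts in muscle, 13967941 to 17826624 in testis, 21465357 to 31140491 in brain and 25339603 to 46332560 in liver. Reads over CpG cytosines per RRBS library ran from 86603853 to 129377470 in muscle, 66753854 to 98127901 in testis, 43018235 to 69500647 in brain and 6970145 to 69689186 in liver, where replicate 2 was the shallowest library.

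The first comparison asks how many genes were detected in each tissue. The most genes with a read were counted in testis. With every library thinned to a total of 11565532 counts, 25072 ± 124 genes (SD, n = 5) had a read in testis, 22429 ± 620 in brain, 18777 ± 1067 in muscle and 18401 ± 325 in liver. Testis exceeded every other tissue and brain exceeded muscle and liver in all libraries. The exact permutation test, two-sided, gave p = 0.00794 for each of these 5 pairs, the smallest that 5 against 5 libraries allow (adjusted over 6 pairs 0.00952). Muscle and liver did not differ detectably (exact permutation p = 0.468); at full depth their order turned, with 19172 ± 1061 in muscle and 19528 ± 234 in liver (SD, n = 5). Thinning matched the total, not the counts left for less abundant genes, and counts were concentrated in few genes in muscle and liver. The 10 most counted genes held 39.7% ± 2.29 of all counts in muscle (SD, n = 5) and 24.3% ± 1.06 in liver, against 3.86% ± 0.569 in brain and 3.09% ± 0.324 in testis. The TMM factors, which rescale library totals for this composition, ran from 0.256 to 0.404 in muscle and from 2.56 to 2.73 in testis, so the numbers of genes detected do not separate breadth from composition.

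**Figure D1:**
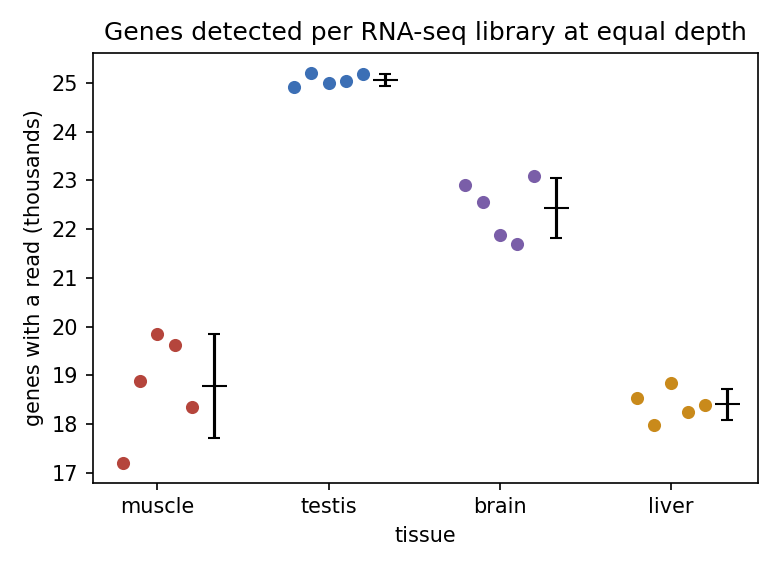
Genes with at least 1 read per RNA-seq library (vertical axis, in units of 1000 genes) in 4 tissues, with every library thinned to 11565532 counts; points are libraries, black bars the mean and SD of 5 libraries. All testis libraries lie above all brain libraries, and all brain libraries above those of muscle and liver.

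The second comparison asks which genes set each tissue apart from the other tissues. Brain had the largest set of enriched genes, 2409 of 22293 tested (10.8%), followed by liver with 1472, testis with 1217 and muscle with 1163. Liver had the most depleted genes, 1908, against 756 in muscle, 476 in brain and 106 in testis. The enriched genes held very different shares of the RNA of their tissue: 82.0% ± 2.47 of counts in muscle (SD, n = 5) and 69.1% ± 0.81 in liver, but 23.4% ± 0.51 in brain and 5.05% ± 0.34 in testis. In libraries of the other tissues the muscle-enriched genes held 2.53% of counts, the liver-enriched genes 2.28%, the brain-enriched genes 0.782% and the testis-enriched genes 0.131%. With library size alone as the scaling, an alternative chosen after seeing the data, 455 genes were enriched in muscle, 3048 in testis, 2504 in brain and 794 in liver. Muscle then had the most depleted genes, 3639, against 2364 in liver, 152 in brain and 17 in testis, so both orders of the tissues depend on the scaling. The folds of the named genes below are under TMM and depend on it too: with library size alone all 16 were still called, in the same direction, but most folds changed.

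**Figure D2:**
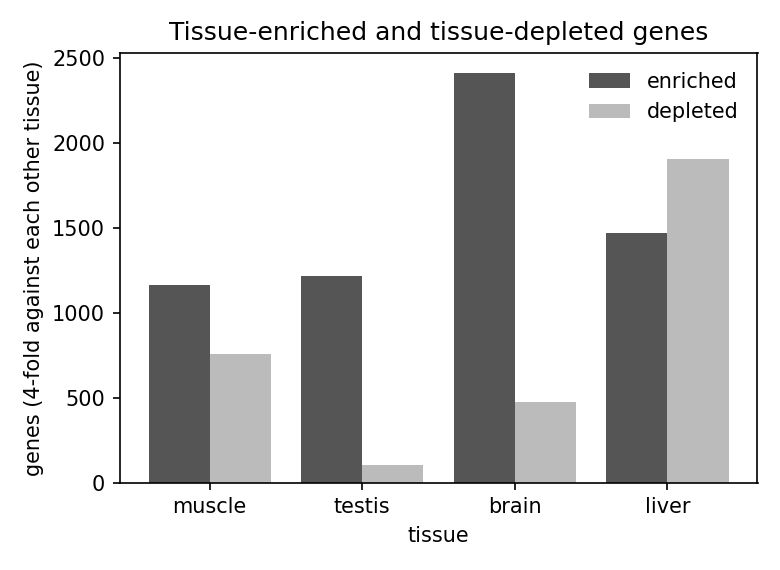
Number of genes (vertical axis) enriched (dark bars) or depleted (light bars) in each tissue, called at least 4-fold against each of the other tissues by edgeR's quasi-likelihood test. Brain has the tallest enriched bar (2409 genes) and liver the tallest depleted bar (1908 genes) under TMM scaling, whereas with library size alone testis has the most enriched (3048) and muscle the most depleted genes (3639).

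In muscle, the gene with the largest smallest-of-3 fold change was DLAgn_00263030 (sequence UN, positions 90664759 to 90667475, plus strand, 10 exons), at 5767 ± 2010 CPM in muscle (SD, n = 5), 23400-fold over testis, where it had 0.247 ± 0.261 CPM. The log2 fold change over testis was 14.52 (SE 1.08), and the largest adjusted p of edgeR's 3 contrasts was 3.59e-09. The log2 value was 11.56 with library size alone and 15.34 without testis replicate 4, which held 0.7017 CPM. DLAgn_00156950, a gene model of 1 exon and 246 bp on LG5 (positions 10623478 to 10623723, minus strand), reached 33780 ± 9066 CPM in muscle, 21700-fold over its level of 1.56 ± 1.24 CPM in testis (log2 14.41, SE 0.84, edgeR adjusted p = 1.36e-10), with 0 reads in brain. Lower in muscle than elsewhere were DLAgn_00078950 on LG18-21 (positions 16244678 to 16257808, 7 exons) and DLAgn_00087630 on LG1A (positions 142555 to 342422, 11 exons), both with 0 reads in the 5 muscle libraries. The former was at least 19.6-fold lower in muscle than in testis (2.29 ± 1.03 CPM; edgeR adjusted p = 4.2e-06). The latter was at least 13.8-fold lower than in liver (1.61 ± 0.901 CPM; edgeR adjusted p = 9.22e-05), but could not be called with 2 tissues in each fit, where it had no value.

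Both testis-enriched genes taken by the naming rule had no read in any other tissue. DLAgn_00236630 (UN, positions 46574040 to 46575211, 3 exons) had 2.12 ± 0.674 CPM in testis (SD, n = 5) and 0 reads in the 15 other libraries, at least 18.2-fold higher in testis (edgeR adjusted p = 9.81e-05). DLAgn_00018270 (LG12, positions 83654 to 95333, 4 exons) had 1.40 ± 0.659 CPM and again 0 reads elsewhere, at least 12-fold higher (edgeR adjusted p = 0.000398). DLAgn_00119820 on LG20 (positions 12789207 to 12794130, 5 exons) was 351-fold lower in testis, at 0.422 ± 0.192 CPM, than in brain, at 147.9 ± 243 CPM with 566.2 CPM in replicate 1 alone, and reached 2180 ± 489 CPM in liver (edgeR adjusted p = 7.8e-06). Its log2 value was -8.43, but -6.67 without brain replicate 1 and -5.97 with library size alone. DLAgn_00117100, also on LG20 (positions 5022396 to 5026769, 6 exons), was 100-fold lower in testis (0.234 ± 0.0990 CPM) than in muscle (23.4 ± 9.02 CPM; log2 -6.61, edgeR adjusted p = 1.14e-09), with a log2 value of -3.74 under library size alone.

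In brain, DLAgn_00041050 on LG14 (positions 12349398 to 12351164, plus strand, 7 exons) reached 5090 ± 2938 CPM (SD, n = 5), 13500-fold over muscle with 0.376 ± 0.302 CPM. It had 0 reads in liver (log2 13.79, SE 0.83; edgeR adjusted p = 1.47e-10). DLAgn_00072590 on LG17 (positions 19195942 to 19197526, 4 exons) reached 399.4 ± 169 CPM, with 0 reads in muscle and liver and 8 reads in all testis libraries, at least 3420-fold higher than the floor of muscle (edgeR adjusted p = 2.88e-09). DLAgn_00097690, a single-exon model on LG1A (positions 27010158 to 27012683), had 0 reads in brain and was at least 410-fold lower there than in testis (4.77 ± 1.91 CPM; edgeR adjusted p = 2.46e-09). DLAgn_00101370 on LG1B (positions 6563422 to 6572998, 11 exons) was 888-fold lower in brain, at 0.0534 ± 0.0569 CPM from 13 reads, than in testis, at 47.4 ± 13.2 CPM (log2 -9.74, and -10.47 to -9.40 with a library left out; edgeR adjusted p = 1.54e-12).

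In liver, DLAgn_00232860 (UN, positions 40263505 to 40265597, 6 exons) had 1439 ± 337 CPM (SD, n = 5), against 1, 7 and 11 reads in all libraries of muscle, testis and brain (log2 14.87 over brain, SE 0.70; edgeR adjusted p = 7.52e-13). DLAgn_00061000 on LG16 (positions 10655969 to 10660410, 7 exons) had 6823 ± 1086 CPM in liver, 29600-fold over testis with 0.230 ± 0.225 CPM (log2 14.81, SE 0.68; edgeR adjusted p = 1.48e-13). DLAgn_00107130 on LG2 (positions 4115349 to 4126075, 9 exons) and DLAgn_00039190 on LG14 (positions 7119894 to 7129160, 9 exons) had 0 reads in liver. They were at least 178-fold and at least 163-fold lower in liver than in testis, where they had 6.13 ± 0.582 and 5.61 ± 0.873 CPM (edgeR adjusted p = 9.2e-12 and 8.96e-11). DLAgn_00039190 reached 271.1 ± 89.5 CPM in muscle.

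Pairs of tissues differed in most genes. Of 22293 genes tested, edgeR called 16395 (73.5%) between testis and liver, 15714 between muscle and brain, 15707 between muscle and testis, 15581 between brain and liver, 14715 between testis and brain and 13775 (61.8%) between muscle and liver. The share of called genes that was higher in the tissue named first was 34.6% for muscle against testis, 39.5% for muscle against brain, 49.5% for muscle against liver, 51.3% for testis against brain, 62.8% for testis against liver and 59.5% for brain against liver. These shares depend on the scaling. With library size alone they were 4.8%, 8.6%, 34.1%, 64.6%, 92.4% and 88.2% in the same order. The median log2 difference over all genes moved between TMM and library size alone, from -0.74 to -3.60 for muscle against testis, from -0.52 to -2.95 for muscle against brain, and from 0.00 to -0.56 for muscle against liver. It moved from 0.05 to 0.46 for testis against brain, from 0.56 to 2.82 for testis against liver and from 0.35 to 2.16 for brain against liver. With DESeq2's size factors the majority turned for muscle against liver (53.3%) and for testis against brain (47.2%, with a median of -0.07). Leaving out a single library turned them as well: without brain replicate 4, 7321 of 14019 genes were higher in muscle than in liver, and without testis replicate 5, 6745 of 14237 were higher in testis than in brain. At 4-fold or more, 2350 genes were higher in muscle than in testis and 5935 lower, 6857 were higher in testis than in liver and 2508 lower, and 6171 were higher in brain than in liver and 2986 lower. For muscle against liver the balance turned at this limit, with 4042 higher in muscle and 3355 lower, while it was 3039 and 5703 for muscle against brain and 3448 and 3423 for testis against brain.

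Fish differed most from each other in brain and least in testis. The BCV over 10305 genes was 0.348 in brain, 0.258 in liver, 0.249 in muscle and 0.187 in testis (5 libraries each). Leaving out any library of a tissue kept brain above the others, at 0.317 to 0.377, and gave 0.221 to 0.27 in liver, 0.225 to 0.271 in muscle and 0.168 to 0.204 in testis; the difference between tissues was not tested.

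The RRBS comparisons ask how CpG methylation differs between the tissues. Over 119177 cytosines with at least 10 reads in all 12 libraries, testis had the highest mean level, 59.0% ± 0.35 (SD, n = 3), followed by muscle with 56.4% ± 0.56, brain with 56.4% ± 0.86 and liver with 53.6% ± 0.55. Tissues differed (exact permutation test of an F statistic, p = 0.000584), but this test includes the library preparation. Within a preparation, muscle was 2.67 points lower than testis and brain 2.79 points higher than liver, with no overlap between libraries in either pair (exact permutation, two-sided, p = 0.1, the smallest that 3 against 3 allow). Without liver replicate 2, brain exceeded liver by 0.902 points over the then larger set of sites (exact permutation p = 0.4). The size of that difference rests on this shallow library and the sites it limits the comparison to. Weighted by reads in place of sites, the difference among the 4 tissues was not detectable (exact permutation p = 0.111). Muscle minus testis was then larger, at -8.56 points (exact permutation p = 0.1), and brain minus liver smaller, at 1.52 points (exact permutation p = 0.8).

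Methylation was low around gene starts and high elsewhere in every tissue. In promoter windows (26717 cytosines) the mean was 17.6% ± 0.30 in muscle, 18.3% ± 0.38 in testis, 16.9% ± 0.21 in brain and 15.7% ± 0.10 in liver (SD, n = 3 each). In exons outside these windows (26965 cytosines) it ran from 63.4% ± 1.38 in brain to 66.8% ± 0.40 in testis, and in introns (16394 cytosines) from 65.3% ± 1.62 in brain to 70.0% ± 0.38 in testis. Outside gene models (49101 cytosines) the level was 73.3% ± 0.31 in testis, 71.1% ± 0.92 in brain, 70.3% ± 0.80 in muscle and 64.8% ± 0.51 in liver. Liver also had the most cytosines of intermediate level: 26.5% of the 119177 lay between 20% and 80%, against 15.8% in brain, 14.5% in muscle and 11.5% in testis. Neither this share nor the level outside gene models was computed without the shallow liver replicate 2, and the contrast of liver with muscle and testis includes the library preparation.

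**Figure D3:**
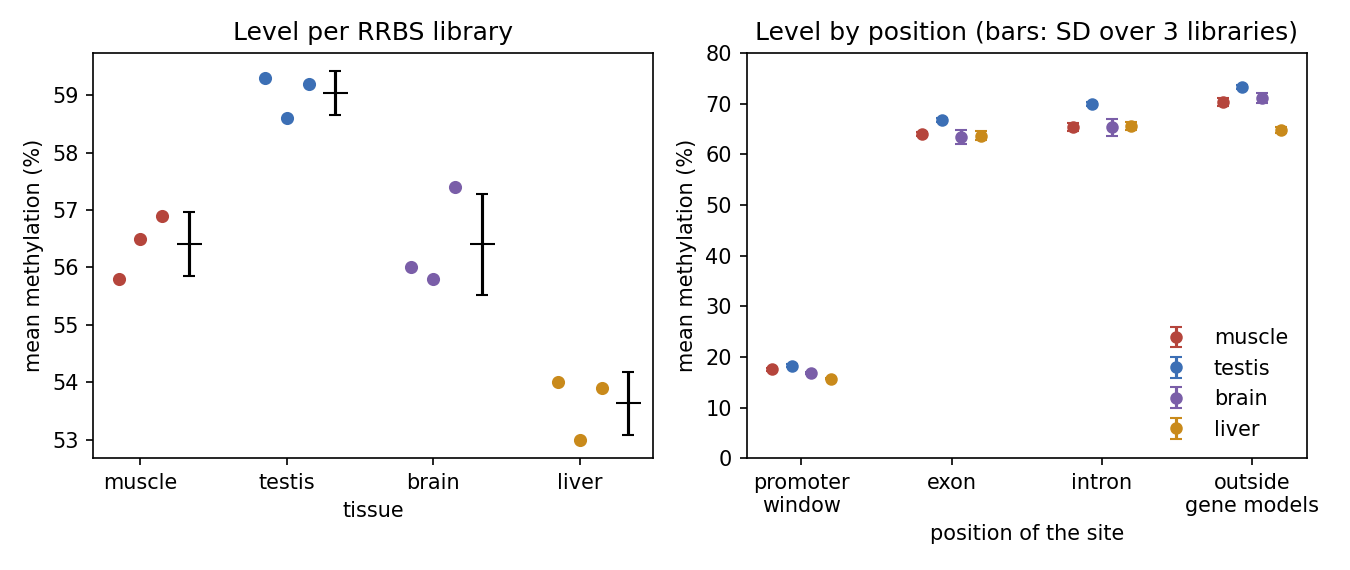
Left, mean CpG methylation (%) of each RRBS library over 119177 cytosines, with the mean and SD of 3 libraries in black and an axis that does not start at 0. Right, mean and SD of 3 libraries by position of the cytosine: promoter windows lie under 20% in every tissue, and outside gene models liver lies lowest at 64.8%.

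Between muscle and testis, which share a library preparation, 7620 of 644380 cytosines (1.18%) were called, with a median of 92 reads per library. Of these, 6069 were higher in testis and 1551 higher in muscle. Without moderation of the dispersion 0 were called, and the sites named below had adjusted p from 0.0886 to 0.0912. Called sites were scarce in promoter windows, which held 18.7% of the tested cytosines but 4.27% of those higher in testis and 3.22% of those higher in muscle, and frequent in introns. Introns held 20.6% of the tested cytosines but 35.9% and 34.4% of the called ones. The largest differences were at 2 cytosines in an exon on LG19 (minus strand, positions 5631797 and 5631800), unmethylated in all muscle libraries (0% ± 0) and fully methylated in all testis libraries (100% ± 0, n = 3 each; adjusted p = 0.00361 and 0.00354), with 67 and 69 reads in muscle and 81 in testis at each. Higher in muscle were a cytosine outside gene models on LG4 (position 21566906, plus strand) and a cytosine in an exon on LG8 (position 22227060, plus strand), with differences of 86.5 and 86.2 points on pooled reads. The former was at 100% ± 0 against 15.4% ± 12.1 in testis (79 and 74 reads, adjusted p = 0.00906). The latter was at 93.5% ± 6.17 against 5.0% ± 2.23 (124 and 141 reads, adjusted p = 0.00383). With the replicate numbers as a block, which pair these tissues, 3926 sites were called, 3434 higher in testis and 492 higher in muscle. None of these 4 sites was called with the block. Adjusted p was 0.0146 on LG4 and 0.0114 on LG8. For the sites on LG19 it was 0.0799 and 0.0804. Testis was wholly methylated there, where the fit with the block is not reliable. For the same reason the number of sites called with the block can be too low. The count of the main test fell to 0 when any testis library was left out and was 5710 to 9820 without a muscle library.

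Between brain and liver, which share the other preparation, 0 of 123719 cytosines were called by the moderated model (smallest adjusted p = 0.0214). At an unadjusted p under 0.05 there were 31678 (25.6%). Fisher's exact test on pooled reads, which ignores the spread between fish, called 5555 higher in brain and 5510 higher in liver.

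In the pairs that cross the preparations, tissue and preparation cannot be told apart. Testis and liver differed at 5243 of 148967 cytosines, 4037 higher in testis and 1206 higher in liver. Of those higher in testis, 59.3% lay outside gene models, which held 39.7% of the tested cytosines. Ordered by the difference on pooled reads, the first site higher in testis was in an exon on LG13 (95.6 points; position 26290734, minus strand; 99.3% ± 1.25 against 6.06% ± 10.5, 326 and 57 reads, adjusted p = 0.00115). The next was in an intron on LG19 (95.3 points; position 17752298, minus strand; 95.3% ± 2.86 against 0% ± 0, 106 and 52 reads, adjusted p = 0.000894). The sites higher in liver lay outside gene models on LG24 (position 4987481; 97.0% ± 5.25 against 15.5% ± 5.59, 46 and 105 reads, adjusted p = 0.00229) and LG9 (position 1666440; 100% ± 0 against 25.1% ± 4.16, 148 and 658 reads, adjusted p = 0.000628; SD, n = 3 throughout). With the replicate block, which pairs these tissues, the sites on LG13 (adjusted p = 0.00838) and LG24 (0.00445) passed, and those on LG19 (0.0348) and LG9 (0.0464) did not. Liver was wholly unmethylated at the LG19 site and wholly methylated at the LG9 site, where the fit with the block is not reliable. The count was 359 without liver replicate 3, 13024 of the then 627054 tested without liver replicate 2, 2311 without liver replicate 1, and 2732, 2299 and 2076 without testis replicates 1, 2 and 3.

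Muscle and liver differed at 438 of 148085 cytosines, 252 higher in liver and 186 higher in muscle. With the replicate block that pairs these tissues 0 were called, but that fit is not reliable where liver is wholly methylated or unmethylated. Of the sites named below, this holds for those on LG8 and LG16. The balance turned at a coverage minimum of 20, with 417 higher in muscle and 243 higher in liver. An exonic cytosine on LG8 (position 22227054, plus strand) was at 95.3% ± 4.09 in muscle and 0% ± 0 in liver (SD, n = 3; 124 and 60 reads, adjusted p = 0.00666). A cytosine in a promoter window on UN (position 50943873) was at 99.7% ± 0.60 in muscle and 2.22% ± 3.85 in liver (195 and 52 reads, adjusted p = 0.00671). Higher in liver were cytosines on LG24 (position 7052911, exon; 95.2% ± 8.25 against 1.04% ± 1.79, 56 and 492 reads, adjusted p = 0.00986) and LG16 (position 21618783, outside gene models; 100% ± 0 against 7.95% ± 1.81, 92 and 549 reads, adjusted p = 0.00362). Leaving out muscle replicate 2 or any liver library gave 0 sites, and leaving out muscle replicate 3 gave 119.

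Testis and brain differed at 586 of 563129 cytosines, 305 higher in testis and 281 higher in brain. The split was less even with the replicate block (187 and 63) and among sites covered in all 12 libraries (77 and 36). A cytosine outside gene models on LG20 (position 814698) was at 96.8% ± 2.86 in testis and 0% ± 0 in brain (116 and 69 reads, adjusted p = 0.00829). An intronic cytosine on LG6 (position 4931010) was at 93.7% ± 5.10 and 0.709% ± 1.23 (187 and 109 reads, adjusted p = 0.008). Higher in brain were an intronic cytosine on UN (position 33759745; 98.9% ± 1.29 against 5.91% ± 2.37, 290 and 260 reads, adjusted p = 0.00523) and a cytosine outside gene models on UN (position 67188111; 90.4% ± 5.24 against 11.5% ± 5.98, 456 and 326 reads, adjusted p = 0.00695; SD, n = 3 throughout). With the block, which does not pair these tissues, only the former of the sites on UN was called (adjusted p = 0.00962). The adjusted p was 0.0114 on LG6 and 0.0103 at the other site on UN. The value of 0.146 on LG20 is not reliable, since brain was wholly unmethylated there. The count was 0 when any testis library was left out and 2 without brain replicate 2. Without brain replicate 1 it was 2388 (1568 higher in testis, 820 in brain) and without brain replicate 3 it was 10026 (8489 higher in testis, 1537 in brain). Muscle and brain differed at 0 of 495995 cytosines by the moderated model (smallest adjusted p = 0.0581), with 55951 (11.3%) at an unadjusted p under 0.05.

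Promoter windows were compared within each preparation. Between muscle and testis, 388 of 9596 promoters (4.04%) were called, 305 more methylated in testis and 83 in muscle. The promoter with the largest excess in testis was that of DLAgn_00129590 (window LG22-25, 9302526 to 9304026), at 96.0% ± 2.93 in testis and 11.9% ± 9.10 in muscle (SD, n = 3; 4 sites, 369 and 494 reads, adjusted p = 0.00115). The next was DLAgn_00036740 (window LG13, 27297321 to 27298821), at 95.1% ± 4.13 and 17.3% ± 8.81 (3 sites, 378 and 503 reads, adjusted p = 0.00105). Under TMM scaling their transcripts went opposite ways; with library size alone the genes named for their promoters were not looked at. The first was lower in muscle than in testis (log2 -3.91, edgeR adjusted p = 0.00185) and the second higher (log2 2.87, edgeR adjusted p = 4.78e-09). The largest excess in muscle was at DLAgn_00194610 (window LG8, 17902107 to 17903607), at 72.8% ± 2.07 against 16.7% ± 0.29 in testis (3 sites, 973 and 543 reads, adjusted p = 0.000612), with a lower transcript level in muscle (log2 -4.13, edgeR adjusted p = 1.08e-06). DLAgn_00021490 (window LG12, 10357198 to 10358698) was at 93.9% ± 8.11 in muscle and 41.4% ± 9.49 in testis (3 sites, 257 and 214 reads, adjusted p = 0.0195). Its call was lost without testis replicate 1 (adjusted p = 0.0697), 2 (0.0655) or 3 (0.158). Without moderation 34 promoters were called, and of the 4 named only DLAgn_00194610 (DLAgn_00129590 0.0678, DLAgn_00036740 0.065, DLAgn_00021490 0.152). The count was 214, 179 and 185 without testis replicates 1, 2 and 3.

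Between brain and liver, 124 of 3440 promoters (3.6%) were called, 101 more methylated in brain and 23 in liver. At a difference of at least 25 points the counts were close to even, 22 and 19, and without brain replicate 3 they were 97 and 49. DLAgn_00198470 (window LG9, 6304473 to 6305973) was at 94.9% ± 3.27 in brain and 31.1% ± 15.4 in liver (SD, n = 3; 4 sites, 3133 and 1706 reads, adjusted p = 4.42e-05), with a lower transcript level in brain (log2 -4.95, edgeR adjusted p = 6.86e-09). DLAgn_00042040 (window LG14, 14077928 to 14079428) was at 75.0% ± 12.7 in brain and 3.06% ± 2.97 in liver (3 sites, 351 and 766 reads, adjusted p = 0.000399). More methylated in liver was DLAgn_00095420 (window LG1A, 21014277 to 21015777), at 62.0% ± 15.2 against 5.12% ± 3.45 in brain (5 sites, 852 and 1218 reads, adjusted p = 0.000833), with a higher transcript level in brain (log2 3.99, edgeR adjusted p = 1.16e-07). The other was DLAgn_00122920 (window LG20, 20740991 to 20742491), at 70.8% ± 23.5 against 8.91% ± 6.15 (3 sites, 1035 and 2081 reads, adjusted p = 0.0017), whose transcript did not differ detectably (log2 0.20, edgeR adjusted p = 0.748). Without moderation 32 were called, all higher in brain, and of the 4 named only DLAgn_00198470 (DLAgn_00042040 0.0605, DLAgn_00095420 0.116, DLAgn_00122920 0.171). Without the shallow liver replicate 2, 9609 promoters could be tested and 211 were called.

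Within each tissue, genes with methylated promoters had lower expression. Across genes, promoter methylation and expression had a Spearman correlation of -0.422 in testis (10562 genes), -0.406 in brain (10110), -0.333 in muscle (9750) and -0.31 in liver (3832; permutation p = 1e-05 in each, the smallest the resamples give, and adjusted p = 1e-05 over the 4 tissues). Most promoters had low methylation: 71.7% of those in testis, 74.2% in brain, 73.8% in muscle and 80% in liver had a mean level under 20%. In testis, mean promoter methylation was 54.1% in the lowest of 5 equal groups of genes ranked by expression and 11.1% in the highest. The values were 49.7% and 9.23% in brain, 37.6% and 11.6% in muscle, and 24.5% and 8.62% in liver. In liver the group above the lowest was higher still, at 29.8%. No read was counted in any library for 13.7% of genes with a promoter over 80% in brain, against 0.733% of those under 20%. In testis these shares were 3.37% and 0.277%, in muscle 24.1% and 6.2%, and in liver 29.3% and 11.1%.

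**Figure D4:**
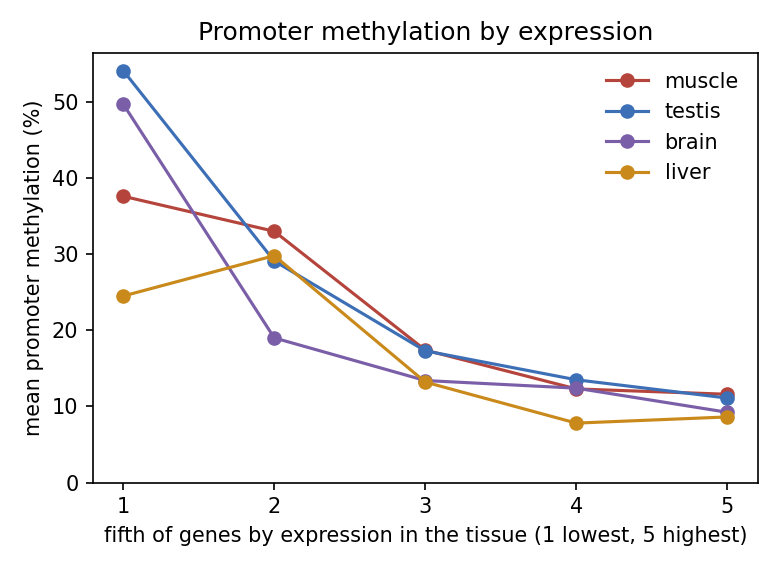
Mean promoter methylation (%, vertical axis) of genes in 5 equal groups ranked by expression within each tissue (horizontal axis, 1 lowest to 5 highest); each line is a tissue, and points are means over genes, without error bars. The lowest group has the highest level in testis (54.1%), brain (49.7%) and muscle (37.6%), while in liver group 2 is highest (29.8%). Liver rests on 3832 genes, limited by its shallow replicate 2.

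The last comparison asks whether promoters that differ between tissues go with transcripts that differ. Over all genes, the Spearman correlation of the promoter difference with the log2 fold change was 0.018 for muscle against testis (8710 genes, permutation p = 0.0919, adjusted 0.0919) and -0.036 for brain against liver (3140 genes, permutation p = 0.0425, adjusted 0.085 over these 2). Unadjusted, from the t approximation over genes, p ranged from 0.000789 (without liver replicate 2, 8782 genes) to 0.874 (without brain replicate 1) for brain against liver. For muscle against testis it ranged from 0.0204 (without testis replicate 3) to 0.415 (without muscle replicate 3), with 0.021 for the narrower window. Among promoters called between muscle and testis whose gene was also called in RNA, 37 of the 49 more methylated in muscle had the lower transcript level in muscle, against 81 of the 167 more methylated in testis (odds ratio 0.305, Fisher's exact test p = 0.000996, adjusted 0.00108). Between brain and liver, 19 of the 32 more methylated in brain had the lower transcript level in brain, against 1 of the 15 more methylated in liver (odds ratio 0.0489, Fisher's exact test p = 0.00108, adjusted 0.00108). Where the promoter was not called, 36.5% of 6060 genes called in RNA were higher in muscle than in testis and 66.8% of 2209 higher in brain than in liver, and these directions rest on TMM scaling.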

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

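The test for samples that stand apart was fixed before the data were examined, and no explanation is weighed for these values. The test was run on 80 sets of 5 values, each a measure in the 5 RNA-seq libraries of a tissue. In 9 of them a library's gap to the nearest other library exceeded 0.71 of the set's range, where chance gives about 4. That expected number takes values as normal. The sets are not independent, since they come from the same 20 libraries, and some rest on few reads.

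Of the values below, those in muscle of DLAgn_00232860 and DLAgn_00061000 are 1 read in all 5 libraries, so that counting alone puts a library apart. DLAgn_00232860 was at 0.2412 CPM in muscle replicate 1 with 0 in the 4 other muscle libraries, and at 0.2047 CPM in brain replicate 1 with at most 0.0353 in the others. DLAgn_00061000 was at 0.1532 CPM in muscle replicate 4 with 0 in the others, and at 0.63 CPM in testis replicate 5 against 0.1029 to 0.1669. DLAgn_00263030 was at 0.7017 CPM in testis replicate 4 against 0.045 to 0.191, and at 0.3709 CPM in brain replicate 4 against 0 to 0.0199. DLAgn_00039190 was at 427.1 CPM in muscle replicate 1 against 200.4 to 255.1, and DLAgn_00119820 at 566.2 CPM in brain replicate 1 against 1.66 to 159.7. Genes enriched in muscle held 3.952% of counts in testis replicate 3 against 3.454% to 3.52% in the other testis libraries.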

How the results depend on the processing

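Scaling by library size alone, merging of strands and full depth for detected genes were chosen after seeing the data; the other alternatives were listed beforehand. No named gene, site or promoter changed sign. The undetected difference in genes with a read between muscle and liver did at full depth (19172 and 19528), and the balance of calls turned in some comparisons. Muscle and liver had 417 cytosines higher in muscle and 243 higher in liver at coverage 20, and with DESeq2's size factors 53.3% of the genes called between muscle and liver were higher in muscle and 47.2% of those between testis and brain were higher in testis. Of the values under other settings for the main results, 160 stayed within the limits of 1.5 times the count or the same side of the threshold, 36 moved, 4 were weaker and 1 was stronger; with a library left out these were 378, 26, 3 and 1. Calls of named sites were less stable, kept 73 times and lost 72 times over all settings, where some losses with the replicate block are not reliable. Those of named promoters were kept 88 times and lost 9 times. Both tallies leave out settings where a site or promoter could not be tested. Every named promoter was left out at a minimum of 10 sites, and all were kept at 25 points by construction. Where no reason is given, the cause was not tested. The gene list tests could not be run, since no identifier matched a name.

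With library size alone, enriched genes numbered 455 in muscle, 3048 in testis and 794 in liver, and depleted genes 3639 in muscle, 17 in testis, 152 in brain and 2364 in liver. At 2-fold, a looser limit by construction, enriched genes numbered 2186 in muscle, 2394 in testis and 2435 in liver, and depleted genes 1906 in muscle, 544 in testis and 1083 in brain. With 2 tissues in each fit, depleted genes numbered 392 in muscle, 269 in brain and 702 in liver. Leaving out a library moved the spread in liver within 0.221 to 0.27.

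By the rule of same-number correlations over 0.1, replicate numbers did not pair the RNA libraries (correlations of deviations from -0.262 to 0.247). With the replicate block the enriched genes numbered 1161 in muscle, 1335 in testis, 2258 in brain and 1474 in liver, and the pairs gave 15725 for muscle and testis, 15423 for muscle and brain, 13650 for muscle and liver, 14610 for testis and brain, 16457 for testis and liver and 15351 for brain and liver. In RRBS the block gave 3926 cytosines for muscle and testis, 0 for muscle and liver, 4859 for testis and liver, and 250 for testis and brain, whose numbers did not pair. These RRBS counts can be too low, since the fit with the block is not reliable where the second tissue is wholly methylated or unmethylated.

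The level difference among tissues had an exact permutation p = 0.111 on pooled reads, where muscle minus testis was -8.56 and brain minus liver 1.52 points. For muscle and testis, 2219 cytosines were called among sites covered in all libraries (fewer sites tested), 53689 by Fisher's exact test and 0 without moderation. For muscle and liver, 660 were called at coverage 20 and 1399 with merged strands. For testis and brain, 113 were called among sites covered in all libraries. For testis and liver, 3099 were called at coverage 20, and for brain and liver 11065 by Fisher's exact test. Fisher's exact test takes no account of the spread between fish. With a library left out, cytosines ranged from 0 to 9820 for muscle and testis, 0 to 329 for muscle and liver, 0 to 10026 for testis and brain, 359 to 13024 for testis and liver and 0 to 1 for brain and liver. For muscle and testis the count was 0 whichever testis library was left out. With any muscle or testis library left out, the difference was 84.7 to 89.1 points at the LG8 site and 78.0 to 92.3 at the LG4 site. At the LG19 sites every library was at 0% or 100%, so the difference could only be -100 points. The highest count for testis and liver came with 627054 tested sites.

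Promoters of muscle and testis numbered 761 by Fisher's exact test, 34 without moderation, 108 with at least 10 sites and 160 at 25 points, and 179 to 460 with a library left out. Promoters of brain and liver numbered 71 at coverage 20, 292 by Fisher's exact test, 32 without moderation, 80 with the narrower window, 77 with at least 10 sites and 41 at 25 points (22 higher in brain, 19 in liver), and 84 to 211 with a library left out. The correlation of promoter and expression change was 0.026 for muscle and testis with the narrower window (0.009 to 0.025 with a library left out). For brain and liver it was -0.013 at coverage 5, -0.049 at coverage 20 and -0.019 with the narrower window (-0.054 to -0.003 with a library left out).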

Other observations

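The tests against other splits of the RNA-seq libraries, on the order of the brain replicates and on the kit were chosen after the results they concern had been seen. The measures of gene span and linkage group were added after seeing the data. Genes enriched in a tissue also differed in genomic span. The median genomic span of brain-enriched genes was 10525 bp, against 7704 bp for all 22293 tested genes, while it was 5376 bp for testis-enriched, 6254 bp for liver-enriched and 6629 bp for muscle-enriched genes. Random lists of the same sizes gave medians with a central range of 7306 to 8065 bp for brain, 7152 to 8233 bp for testis, 7210 to 8201 bp for liver and 7116 to 8282 bp for muscle. These ranges leave out the outermost lists at each end. On LG14, 126 of 872 tested genes (14.4%) were enriched in brain (odds ratio 1.42, Fisher's exact test, adjusted p = 0.0223 over 100 tests). On UN, 311 of 3585 (8.68%) were enriched in liver (odds ratio 1.44, adjusted p = 7.11e-06) and 281 (7.84%) in brain (odds ratio 0.663, adjusted p = 1.16e-08). Fisher's exact test takes genes as independent. Enriched genes on linkage groups lay next to each other more often than random placement gave (below), so these p-values can be too small.

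A hypothesis that promoters of tissue-enriched genes are less methylated in the tissue of enrichment was tested within each preparation. Promoters of 393 muscle-enriched genes were lower in muscle than in testis by a mean difference of -4.73 points (25% in muscle, 29.7% in testis; random lists -2.05 to -0.687), those of 429 brain-enriched genes were lower in brain than in liver (-0.989 points; random lists -0.385 to 0.81), and those of 112 liver-enriched genes were lower in liver than in brain (-3.17 points; random lists -1.42 to 1.06). Promoters of 346 testis-enriched genes were at 33.8% in testis and 31.5% in muscle (2.23 points, random lists 0.648 to 2.07). The predicted lower level was thus not seen for testis. Over all 8710 genes promoters were 1.34 points higher in testis, at a mean of 19.7% there. Random lists were not matched for methylation level, so the test cannot tell an effect of enrichment from the higher level of these promoters. The ranges given for random lists are central ranges that leave out the outermost lists at each end. The testis value lay at percentile 99.0 of 10000 lists.

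Genes enriched in the same tissue lay next to each other more often than random placement gave: 767 of 18684 neighbouring pairs, against a mean of 419 and a highest value of 470 in 1000 placements. The longest runs were 8 liver-enriched genes on LG4 (19524661 to 19580628) and 6 muscle-enriched genes on LG6 (964009 to 1067610). Genes annotated as several neighbouring models could give such pairs: 60.2% of the pairs were on the same strand (50.4% of all pairs), 29.2% were under 1000 bp apart (26.0%) and 18.3% overlapped (9.64%), which leaves split models open. Reads shared between overlapping genes or close copies, and shared regulation of neighbours, were not tested.

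By the rule of same-number correlations over 0.1, replicate numbers paired muscle, testis and liver in RRBS, but not brain. A weaker pairing of brain with testis (0.11, 0.02 and 0.06) is left open. Another order of the brain numbers alone gave no such pairing: under the best of 6 orders the lowest correlation with the other tissues was -0.001. In the order given the lowest was -0.04. No brain correlation with another tissue exceeded 0.11, so another order along with weaker correlations is left open. Liver libraries made with the same kit paired with muscle and testis at 0.11 or more, so the kit did not remove pairing in liver. That was seen before the test was chosen, and a weakening by the kit is not excluded. That the brain libraries came from other fish, or that methylation varied between fish in another way in brain, stays open and was not tested.

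At CpGs with at least 10 reads on each strand, 2.82% to 8.51% per library differed by over 50 points between strands. Low coverage could explain part of this: with 30 reads on each strand the share was 0.438 of that with 10 (median of 12 libraries). Unmethylated bases filled in at fragment ends could explain another part, since CpGs higher on a strand were covered only on the side that fill-in needs at least 2.18 times as often as CpGs methylated on both strands. Neither value decides, and no biological explanation was tested.

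The real grouping was compared with other splits of the libraries. In 50 splits of the 20 RNA-seq libraries, only the real split (1 of 50) gave as many genes for each of the 4 enriched sets (1163 in muscle, 1217 in testis, 2409 in brain and 1472 in liver, with 0 as the highest other) and for each of the 6 pairs of tissues (highest other 4907 for muscle against testis, with 15707 in the real split, and 0 for the others). A share of 1 of 50 is the smallest that these splits can give. The other splits mix tissues within a group, which raises its spread, so they do not test the size of the sets. The 10 splits of 6 RRBS libraries are too few for a share under 0.05. The real split called 7620 cytosines for muscle against testis, 438 for muscle against liver, 586 for testis against brain and 5243 for testis against liver, and 388 and 124 promoters, with 0 as the highest other in each (1 of 10). For muscle against brain and brain against liver, where the real split called 0, all 10 of 10 splits gave as many, with 0 and 6 as the highest other.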
